A study of Saccharomyces cerevisiae with 32 samples.

How the data were processed

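RNA from synchronised cultures of Saccharomyces cerevisiae was measured on 32 Agilent 2-colour arrays. Per the labels, cells were held in G1 with the mating pheromone alpha-factor, released, and sampled every 15 min from 0 to 105 min. The control strain (WT) carried epitope tags on the transcription factors Hcm1, Tos4, Yox1 and Yhp1. The other strain (4P, called a phosphomutant by the submitters) carried the same tags on mutant forms of all 4 proteins. Each of the 16 groups (2 genotypes at 8 times) held 2 arrays, and the arrays of a genotype and replicate number form 1 time course, so there were 4 time courses. The other channel of every array held RNA of an untagged strain in mid-log growth. Per the labels, total RNA was amplified by in vitro transcription and coupled to Cy3 or Cy5. The synchronised RNA was in Cy3 in replicate 1 and in Cy5 in replicate 2, so that the dye effect cancelled in each group mean. With 1 array of a group left out it no longer cancels there, so such fits mix the dye effect with the loss of the array.

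The deposited scanner files were made with Agilent Feature Extraction 10.7.1.1, per the submitters' processing notes. They hold, per the file headers, median signal and median background intensity per channel on a linear scale, and a log10 ratio of red over green. A mean signal had been planned as the starting value before the data were examined, but the columns used here are medians. The deposited table of the whole series holds values on a log2 scale with column medians between -0.04 and 0.02. Its values correlated with the scanner's log ratio across probes at r = 0.961 to 0.999 per array, in the direction of synchronised sample over reference, and which normalisation and centring step gave them is not given in the sources used here. Gene names came from the array's annotation columns and a RefSeq gene table of the assembly R64. The array's own annotation uses an older genome build, so no coordinates are given. Of 6225 systematic names on the array, 5737 matched that table and 488 kept the name in the file.

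Each array held 12512 spots that were not controls, for 6256 probes with 2 spots each. Background was corrected with normexp (offset 50) in limma 3.58.1 under R 4.3.3, followed by loess within each array, with control spots and outlier-marked spots at weight 0. Outlier-marked spots were then set to missing, the spots of a probe averaged, and all ratios turned to synchronised sample over reference. Probes of the same gene were averaged for the 29 genes with several probes, of which 9 had a pair of probes correlating below 0.5 over the arrays. Probes kept were those well above background in the synchronised channel on at least 1 whole group, which left 6236 probes and 6205 genes, 5729 of them with a value on all 32 arrays.

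The arrays differed in quality. Between 94.8% and 99.6% of spots were well above background in the synchronised channel, and the median signal was 6.67 to 81.5 times background there and 4.90 to 79.1 times in the reference channel. The number of outlier-marked spots had a median of 9 and reached 1761 on the 4P array at 105 min, replicate 1, where duplicate spots correlated at r = 0.525. The 4P array at 15 min, replicate 1, had the next most. Replicates correlated across genes between r = 0.586 (4P at 105 min) and r = 0.918 (4P at 45 min). The 2 arrays per group limit the precision. The arrays lay on 5 slides, and scan days followed the slides. Slide 1 held the 4P arrays at 15 and 105 min of replicate 1, slide 2 held WT replicate 1 except 45 min, slide 3 held WT replicate 2 except 0 min, and slide 4 held all of 4P replicate 2. Slide 5 held the rest of 4P replicate 1 with WT at 45 min of replicate 1 and WT at 0 min of replicate 2. Slide and genotype therefore largely coincided, and the genotypes met on 1 slide within a replicate at 45 min of replicate 1 alone.

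Group means were fitted with limma over all 32 arrays, with moderated F tests for change over the 8 times in each genotype, for a difference between genotypes at any time, and for a difference that depended on time, and moderated contrasts at each time. Differences are 4P minus WT on the log2 scale, with the standard error (SE) of the fit. P values were adjusted by the Benjamini-Hochberg method over the genes tested, separately for each contrast, at 0.05. The shift over the whole course used the mean of each of the 4 time courses as 1 value. For 18 gene lists drawn up before the data were examined (273 entries, all on the array), the mean log2 ratio per array was tested with the same model, with p values adjusted over 18 lists at 8 times. The camera test with a preset correlation of 0.01 and with an estimated correlation was the alternative for lists. The lag between time courses was a shift from -30 to 30 min in steps of 1 min. It was the shift with the highest correlation over time within a gene, averaged over genes, after linear interpolation.

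The genes named were chosen by a rule written before the data were examined. It names the 4 mutated genes and CLN2, CLB2, CLB5, WHI5, NDD1, CLN3, SWI4, CDC20, CDC5 and SIC1 in every case. For change over time in WT it adds the 2 changing members of each list with the largest range, and the 5 largest ranges outside the lists. For 4P against WT it adds up to 3 members of each list that differed at any time, with the largest difference of one sign in both replicates, the 6 highest and 6 lowest differences at a single time, and any gene with a shift over the course. Of the 18 lists 1 is not described, nor are the genes that the rule names from that list alone. Other genes named below were picked after their values were seen, from the genes called at a time, the genes whose difference depended on time, or the members of a list that moved.

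The series text ties the replicate number to the dye orientation of the experiment, so same-numbered arrays share a dye orientation and a block on the number removes what differs between the orientations. The labels do not say that same-numbered WT and 4P courses were grown or hybridised together, and most lay on different slides. As a check, deviations of same-numbered WT and 4P arrays from their group means correlated across genes at r = 0.05 to 0.37 over the 8 times, with a median of 0.33, against a median of 0.30 over all pairs of replicate 1 arrays of any group. The value with a replicate block is therefore given beside a result where it changed the call or moved a count by over 1.5 times. Nothing in the labels says how far the cultures of one genotype were independent beyond being separate experiments, and each genotype was 1 strain.

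Alternatives fixed before the data were examined were the scanner's log ratios, the deposited series values, median centring in place of loess, Aquantile between arrays, no filter and a stricter filter on dim probes, the brightest probe per gene, the replicate block, slide as a block, time course as a random block, limma with trend and robust settings, both camera tests, all arrays taken as independent for the course shift, and leaving out each array in turn. Slide as a random block, the removal of each array's trend with gene length, the fit without the 2 arrays with the most outlier marks, and the sulfur list without MET17 were added after seeing the data.

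The steps were tested on simulated data. The simulated noise was independent between genes, and outside the course shift test also between arrays, with no dye or slide effect. In the real arrays slide and genotype largely coincided, so the low numbers of false calls here do not carry over to them. In 1 run, 100 of 5729 genes were changed at 75 min by 1 on the log2 scale and another 100 by 2. Of these, 80 and 100 were called, with 11 unchanged genes called. For the course shift 82 and 99 of 100 were called with 7 unchanged ones, and for change over time in WT 77 and 100 with 9. A list shift of -0.5 was estimated at -0.44 and called, with no other list called, and a lag of 5 min was found as 4 min.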

Results

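Transcript levels were followed through the cell cycle in a control strain of budding yeast (WT) and in a strain with mutant forms of the transcription factors Hcm1, Tos4, Yox1 and Yhp1 (4P). The question was how phosphomutant forms of these S-phase factors, whose regulation the series title ascribes to the kinase Cdk1, change transcription. Both strains were released from an alpha-factor arrest in G1 and sampled every 15 min from 0 to 105 min, with 2 arrays in each of 16 groups and 32 arrays in all. Values are log2 ratios of the synchronised sample over a common reference from an asynchronous untagged strain, and differences are 4P minus WT with the standard error (SE) of the fit. Adjusted p values come from limma with the Benjamini-Hochberg method. Of 6205 genes tested, the median SE of a difference was 0.19 at each time, from 2 arrays per genotype, a number that limits the precision. The main fit has no replicate block, so this SE also holds what differs between the 2 dye orientations.

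Release from G1 arrest set off an ordered series of transcript waves in WT. Pheromone response genes were highest at 0 min, with ASG7 at 5.01 and the mating agglutinin gene AGA1 at 4.20, and both then dropped, with ranges over the course of 6.38 and 6.28. Genes of the MBF type, which serve DNA replication, peaked at 15 min, led by the S-phase cyclin gene CLB6 (3.80, range 4.68) and the cohesin subunit gene MCD1 (2.37, range 4.24). Core histone genes peaked at 30 min, where HTA1 reached 1.08 with a range of 3.81. The CLB2 cluster of mitotic genes had its highest mean at 45 min (in WT replicate 2 it was higher still at 105 min), led by the cyclin gene CLB1 (range 4.40) and the transcription factor gene SWI5 (range 4.18). Early cell cycle box genes, which carry a promoter element bound by Mcm1, were highest at 60 min. A second G1/S wave followed, since HO and CLN2 were highest in WT at 75 min at 2.00 and 1.49.

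Among the genes named in every comparison, the cyclin gene CLB5 peaked in WT at 15 min (2.09, range 2.63) and CLB2 at 45 min (1.97, range 3.48). In WT the polo kinase gene CDC5 peaked at 45 min (1.25, range 3.02) and the Cdk inhibitor gene SIC1 at 60 min (1.15, range 2.33). SWI4 peaked at 15 min (2.28, range 2.54), NDD1 at 30 min (0.80, range 1.97), CDC20 at 45 min (1.03, range 2.23) and the G1 cyclin gene CLN3 at 60 min (0.38, range 0.91). TOS4 and WHI5 did not pass the test over time in WT (adjusted p = 0.316 and 0.992). WHI5 was well above background on 14 WT and 11 4P arrays, not on all, so its flat course rests in part on dim signals. Further genes with large ranges were HTA2 at 3.75 among histone genes and CLN1 at 3.84 among SBF-type genes. FKH1 at 2.45 and STU2 at 2.14 led the Hcm1 targets, SPC97 at 2.02 and KAR3 at 1.97 the spindle and kinetochore genes, and CDC6 at 2.57 the early cell cycle box genes. Outside the lists the largest ranges were 5.95 for PRM6, 4.22 for YGP1, 4.07 for AIM44, 3.99 for ACM1 and 3.92 for HXT6.

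Lists outside the cell cycle machinery moved too. Stress response genes peaked at 15 min, with HSP42 at 1.95 and the trehalose synthesis gene TSL1 ranging over 3.41. Sulfur assimilation genes peaked at 45 min with MET3 at 3.26 and MET14 at 2.32. Phosphate genes peaked at 60 min with the acid phosphatase genes PHO3 at 1.52 and PHO12 at 1.33. Ribosome biogenesis genes peaked at 45 min, where RPA135 stood at 0.54 and DBP2 at -0.18. Smaller ranges were found for IME1 (0.96) and NDT80 (0.74) among the alpha and meiotic cell genes, RAD54 (1.04) and RNR3 (0.76) among the DNA damage genes, RPL25 (0.99) among ribosomal protein genes and ADE2 (1.73) among strain markers. The mean of 15 of the 18 lists changed over time in WT. Ribosomal protein genes, DNA damage response genes and strain marker genes did not, with adjusted p values of 0.589, 0.0578 and 0.862.

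In numbers, 2210 genes changed over time in WT and 2506 in 4P, 1765 of them in both (3117, 3414 and 2512 with a replicate block). All 23 CLB2 cluster genes, all 18 pheromone response genes, all 11 early cell cycle box genes and all 8 histone genes changed in both genotypes. Of 28 MBF-type genes 26 changed in WT and 27 in 4P (28 and 28 adjusted over the list alone), and of 16 SBF-type genes 15 changed in each (15 and 15 adjusted over the list alone). Of 10 Hcm1 targets 7 changed in WT and 8 in 4P, the same when adjusted over the list alone. Among 40 spindle and kinetochore genes 29 changed in WT and 23 in 4P, again the same adjusted over the list alone.

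**Figure D1:**
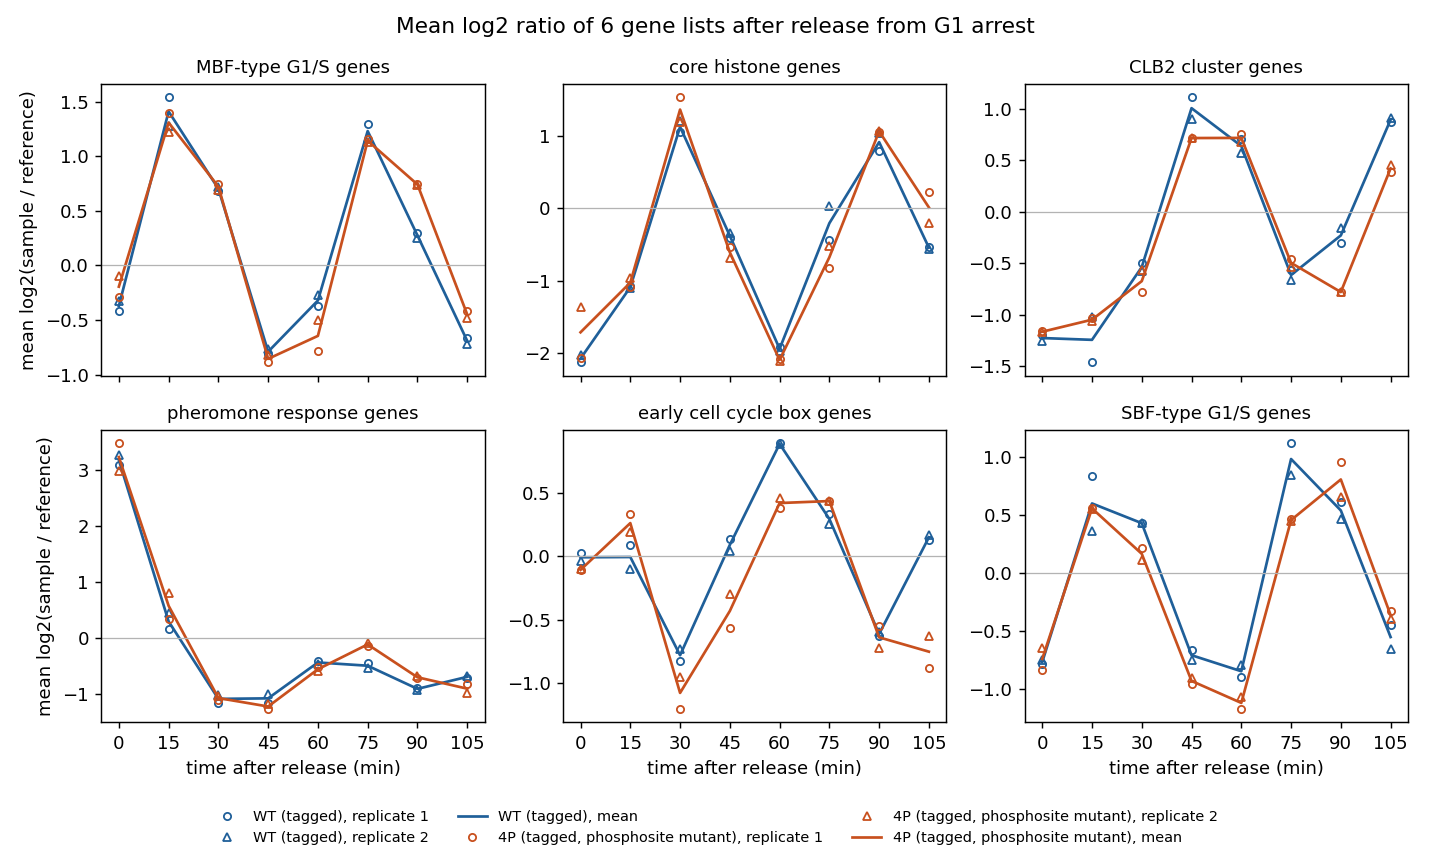
Mean log2 ratio of sample over reference (vertical axes) against minutes after release for 6 gene lists, with a point per array and lines through the means of WT (blue) and 4P (orange). Early cell cycle box genes lie lower in 4P at 45, 60 and 105 min, by -0.52, -0.46 and -0.90.

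In 10 of the 18 lists the highest time was the same in all 4 time courses (6 with the scanner's log ratios), and in 11 it was the same for the means of the genotypes. SBF-type genes peaked at 75 min in both WT courses and at 90 min in both 4P courses, and DNA damage genes at 75 min in both WT courses and at 90 and 105 min in 4P. In the other 6 lists the courses of at least 1 genotype did not agree. Early cell cycle box genes peaked at 60 min in both WT courses and at 75 and 60 min in 4P replicates 1 and 2, and CLB2 cluster genes at 45 and 105 min in WT and 60 and 45 min in 4P. The mutated transcription factor genes peaked at 15 and 90 min in WT and at 15 min in both 4P courses, spindle and kinetochore genes at 30 and 90 min in WT and at 30 min in both 4P courses, and strain markers at 45 and 0 min in WT and 90 and 15 min in 4P. Ribosomal protein genes were highest at 0 min in all courses but 4P replicate 1 (105 min). A single shift of the whole course was small, since both 4P replicates matched the mean WT course best when taken 1 min later. The correlation over time was then r = 0.775 and 0.826, averaged over 2026 genes, which are not independent replicates. Between the WT replicates the best match was at 0 min (r = 0.851). That value compares single courses over genes chosen for change in WT, so it is not on a par with the 4P values. Samples from 4P at 30, 60, 90 and 105 min matched WT best at 28, 57, 85 and 101 min.

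Of the mutated genes, YHP1 had a lower signal in 4P. These loci were tagged in both strains and mutated in 4P. Whether their probes cover altered sequence was not examined, so the signal may not be a plain transcript level. TOS4 and YHP1 lay below the untagged reference on all 32 arrays. Yhp1 and Yox1 are homeodomain repressors, Hcm1 is a forkhead activator and Tos4 a forkhead-domain protein. YHP1 fell in 4P at 30 min (-0.88 ± 0.16 SE, adjusted p = 0.0255), at 45 min (-0.85, adjusted p = 0.0263) and at 90 min (-0.90 ± 0.16, adjusted p = 0.0486), lower in both replicates each time. YOX1 differed by -1.53 ± 0.40 at 30 min, from 1.26 in WT to -0.26 in 4P (adjusted p = 0.231, and 0.0107 with a replicate block). HCM1 differed by -0.78 ± 0.40 at 75 min (adjusted p = 0.239, and 0.0475 with a replicate block) and TOS4 by -0.75 ± 0.37 at 60 min (adjusted p = 0.975). As a list, the 4 genes fell at 30 min by a mean of -0.86 ± 0.25 (adjusted p = 0.0445, and adjusted p = 0.183 with an estimated correlation). All 4 were lower, 1 over all genes and 2 adjusted over the list alone. With a replicate block the list also passed at 45 min (-0.70, adjusted p = 0.022) and 75 min (-0.64, adjusted p = 0.0363). Slide and genotype overlapped, and with slide as a block the list stood at -0.56 at 30 min (adjusted p = 0.19), YHP1 at -0.64 at 90 min (adjusted p = 0.542) and TOS4 at 0.13. The list's call at 30 min was lost without any 1 of 19 of the 32 arrays (values from -1.04 to -0.67, highest adjusted p 0.181), and that of YHP1 at 90 min without any 1 of 23 (highest adjusted p 0.879). Median centring ended the list's call (adjusted p = 0.0625), and YHP1 at 90 min had an adjusted p = 0.16 with the scanner's log ratios, 0.248 with median centring and 0.0888 with a stricter filter on dim probes.

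**Figure D2:**
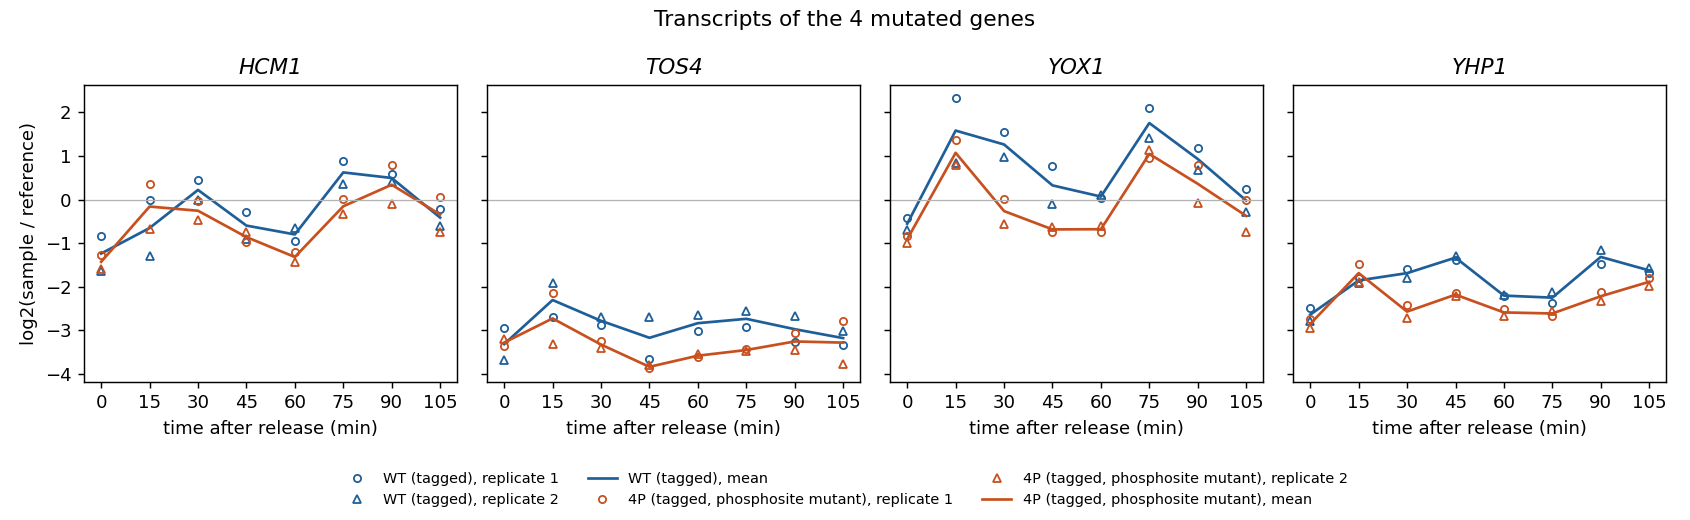
Log2 ratio of sample over reference (vertical axes) of HCM1, TOS4, YOX1 and YHP1 against minutes after release, with a point per array and lines through the means of WT (blue) and 4P (orange). YHP1 lies lower in 4P at 30, 45 and 90 min, by -0.88, -0.85 and -0.90.

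Early cell cycle box genes showed the clearest fall in 4P. In WT they rose around the M/G1 boundary, and in 4P their mean was lower by -0.52 ± 0.10 at 45 min, -0.46 ± 0.10 at 60 min and -0.90 ± 0.10 at 105 min (adjusted p = 0.00296, 0.00594 and 5.7e-06, n = 11 genes). Genes of the MCM helicase, which is loaded at replication origins, led the fall at 105 min, with MCM7 at -1.67 ± 0.21 (adjusted p = 0.000244), MCM5 at -1.29 ± 0.17 (adjusted p = 0.000292), MCM2 at -1.22 ± 0.18 (adjusted p = 0.000791) and MCM4 at -1.20 ± 0.27 (adjusted p = 0.0492). CDC20, an activator of the anaphase-promoting complex, fell by -1.04 ± 0.19 at that time (adjusted p = 0.00861). MCM7 fell by -1.28 at 45 min and MCM5 by -1.04 at 60 min as well. At 105 min all 11 genes were lower, 5 over all genes and 10 adjusted over the list alone, while CLN3 at -0.62 ± 0.17 and SWI4 at -0.21 did not pass over all genes (adjusted p = 0.178 and 0.789). At 45 min 10 genes were lower (1 over all genes, 4 adjusted over the list alone) and at 60 min 9 (1 and 6). CDC6, which loads the MCM complex, went the other way early and rose by 1.05 ± 0.16 at 15 min (adjusted p = 0.00522) and by 0.84 at 75 min.

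With an estimated correlation the list kept adjusted p = 0.0322, 0.0322 and 0.00171 at 45, 60 and 105 min. With slide as a block the early cell cycle box list was at -0.57, -0.52 and -0.96 (adjusted p = 0.0169, 0.0707 and 0.00448). On the slide that held both genotypes at 45 min it differed by -0.71, against -0.33 across slides in replicate 2. Slide as a block left MCM7 at -1.80 (adjusted p = 0.0186) and MCM5 at -1.44 (adjusted p = 0.00261) but ended the calls of MCM2 (-1.29, adjusted p = 0.133), CDC20 (-1.15, adjusted p = 0.327) and CDC6 at 15 min (0.94, adjusted p = 0.465). Omitting single arrays ended the list's call at 45 min without 4P replicate 1 of that time (-0.38, adjusted p = 0.0576) and at 60 min without 4P replicate 1 (adjusted p = 0.0591). CDC20 lost its call without either WT array at 105 min or 4P replicate 1 (values to -0.75, highest adjusted p 0.39), and CDC6 at 15 min without WT replicate 2 (adjusted p = 0.149). The scanner's log ratios also ended the calls of CDC20 (adjusted p = 0.0782) and CDC6 (adjusted p = 0.0861).

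**Figure D3:**
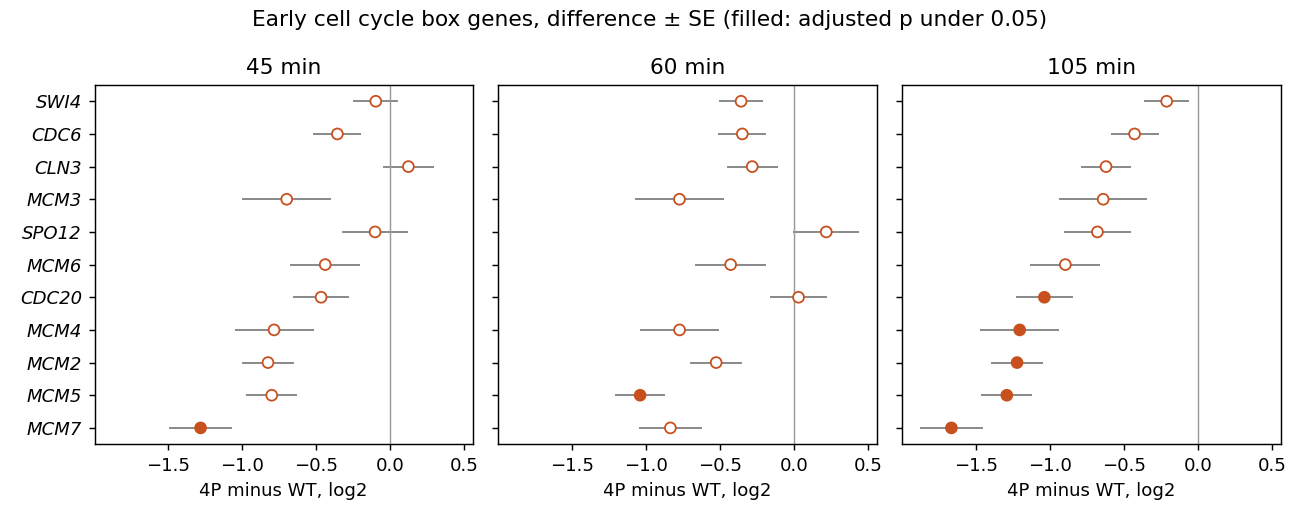
Difference of 4P minus WT (log2, horizontal axes, bars ± SE) for the 11 early cell cycle box genes at 45, 60 and 105 min, with filled points for genes whose adjusted p was under 0.05. At 105 min all 11 points lie below 0 and 5 are filled, from CDC20 at -1.04 to MCM7 at -1.67.

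Mitotic genes of the CLB2 cluster, which are driven by Mcm1 with Fkh2 and Ndd1, were lower in 4P in the second cycle. Their mean fell by -0.55 ± 0.11 at 90 min and -0.47 ± 0.11 at 105 min (adjusted p = 0.00296 and 0.00632, n = 23 genes). CDC20 and SPO12 are also in the early cell cycle box list, so the falls of both lists at 105 min share these genes. KIP2 and ASE1 are also among the spindle and kinetochore genes. With an estimated correlation the CLB2 cluster had an adjusted p = 0.0135 at 90 min and 0.0631 at 105 min. Samples from 4P at 90 and 105 min matched WT best at 85 and 101 min, and a difference in stage was not tested for this list. At 90 min 22 genes were lower, 0 over all genes in limma (401 of all genes had an unadjusted p under 0.05) and 19 adjusted over the list alone. Among them were ALK1 at -1.10, SWI5 at -0.85 and CLB2 itself at -0.64. At 105 min all 23 were lower, 3 over all genes and 9 adjusted over the list alone. The mitotic exit kinase gene DBF2 fell by -1.28 ± 0.13 (adjusted p = 2.1e-05) and the cell wall sensor gene WSC4 by -1.44 ± 0.26 (adjusted p = 0.00627), beside CDC20. DBF2 also fell at 45 min by -0.90. CDC5 differed by -0.51 ± 0.16 at 90 min (adjusted p = 0.352). CLB2 was at 0.86 ± 0.22 at 15 min, when it is at its lowest in WT (adjusted p = 0.0968, and 0.0269 with a replicate block).

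With slide as a block the CLB2 cluster was at -0.64 and -0.56 (adjusted p = 0.0588 and 0.109), DBF2 at -1.20 (adjusted p = 0.0186) and WSC4 at -1.70 (adjusted p = 0.132). The cluster's call at 105 min ended without 4P replicate 1 or WT replicate 2 of that time (highest adjusted p 0.0559), and that of WSC4 without WT or 4P replicate 1 (highest adjusted p 0.165).

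At 60 min 28 genes differed and 27 of them were lower in 4P. SIC1, the Cdk inhibitor gene, fell by -0.83 ± 0.18 (adjusted p = 0.0398) and YRO2 by -1.77 ± 0.27 (adjusted p = 0.00191). The highest SIC1 level in 4P was 1.23 at 75 min, against 1.15 at 60 min in WT. NCA3 and YGP1 fell as well, by -1.45 and -1.39. Slide as a block ended the calls of SIC1 (-0.72, adjusted p = 0.207) and YRO2 (-1.60, adjusted p = 0.13). The SIC1 call was lost without any 1 of 8 arrays (-1.05 to -0.60, highest adjusted p 0.533) and with the scanner's log ratios (adjusted p = 0.11), and that of YRO2 without 4P replicate 2 at 60 min (adjusted p = 0.0621). The count of 28 was 43 with a replicate block and 4 with slide as a block. It was 14, 11, 11 and 4 without WT replicate 2, WT replicate 1, 4P replicate 1 and 4P replicate 2 at 60 min.

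Genes of the second G1/S wave differed in opposite directions at 60 and 90 min. MBF-type genes were lower at 60 min by a mean of -0.32 ± 0.09 and higher at 90 min by 0.47 ± 0.09 (adjusted p = 0.0445 and 0.00355, n = 28 genes). For these genes the adjusted p = 0.0636 at 60 min and 0.0135 at 90 min with an estimated correlation. At 60 min 25 of the 28 were lower, 0 over all genes in limma (321 of all genes had an unadjusted p under 0.05) and 5 adjusted over the list alone. The sliding clamp gene POL30 was at -0.96 and the histone regulator gene SPT21 at -0.57. At 90 min all 28 were higher, 0 over all genes (401 unadjusted) and 10 adjusted over the list alone. The cohesin gene SMC3 was at 0.79 ± 0.18 (adjusted p = 0.133, and 0.0396 with a replicate block) and the primase gene PRI2 at 0.70 ± 0.20 (adjusted p = 0.265, and 0.0396 with a replicate block). The mismatch repair gene MSH6 was at 0.68 ± 0.18 (adjusted p = 0.205) and CLB5 at 0.45 ± 0.12 (adjusted p = 0.227). SWI4, which encodes the DNA-binding part of SBF, was at 0.41 ± 0.15 at 90 min (adjusted p = 0.539).

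SBF-type genes, which serve budding and the cell wall, fell at 75 min by a mean of -0.53 ± 0.13 (adjusted p = 0.0116, n = 16 genes, and adjusted p = 0.434 with an estimated correlation). Of these 13 were lower, 4 over all genes and 7 adjusted over the list alone. The list peaked at 75 min in both WT courses and at 90 min in both 4P courses. A difference in stage was not tested for it. The cell wall gene SRL1 fell by -2.00 ± 0.30 (adjusted p = 0.00232), the glucan synthase gene FKS1 by -0.89 and the polarity gene GIC1 by -0.80. CLN2 was at -0.86 ± 0.25 (adjusted p = 0.0538, and 0.0252 with a replicate block). GIC1 stood at -0.82 ± 0.20 at 30 min (adjusted p = 0.179). With slide as a block, MBF-type genes were at -0.38 at 60 min and 0.41 at 90 min (adjusted p = 0.112 and 0.109). In the same fit SBF-type genes were at -0.58 at 75 min (adjusted p = 0.0707) and SRL1 at -2.17 (adjusted p = 0.0349). The MBF call at 60 min was lost without any 1 of 18 arrays (-0.47 to -0.18, highest adjusted p 0.295). The SBF call ended without WT replicate 1 or either 4P array at 75 min (highest adjusted p 0.124), and that of SRL1 without WT replicate 1 (adjusted p = 0.0857). Median centring ended the calls of MBF-type genes at 60 min (-0.28, adjusted p = 0.177) and of SBF-type genes (-0.42, adjusted p = 0.0653). The scanner's log ratios ended that of MBF-type genes at 60 min (-0.27, adjusted p = 0.148).

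Histone genes and Hcm1 targets did not pass as lists. The histone list did not pass at any time in limma (lowest adjusted p 0.0786 at 105 min, at 0.55 ± 0.19). All 8 genes were higher there, 0 of them over all genes in limma (529 of all genes had an unadjusted p under 0.05) and 3 adjusted over the list alone. HTB2, which encodes histone H2B, fell by -1.22 ± 0.21 at 75 min (adjusted p = 0.00695). That call was lost without WT replicate 1 or 4P replicate 2 of that time (highest adjusted p 0.125) and with slide as a block (-1.22, adjusted p = 0.182). Hcm1 targets were at -0.19 ± 0.08 at 75 min with all 10 lower (adjusted p = 0.142, and 0.0363 with a replicate block), 1 over all genes and 1 adjusted over the list alone. Among them FKH1 was at -0.57 ± 0.15 at 90 min (adjusted p = 0.227), NDD1 at -0.44 ± 0.18 at 30 min (adjusted p = 0.348) and WHI5 at 0.13 ± 0.14 at 60 min (adjusted p = 0.989). WHI5 was dim, being well above background on 14 WT and 11 4P arrays, which limits its ratios. Spindle and kinetochore genes did not pass at any time (-0.13 ± 0.05 at 90 min, adjusted p = 0.115, with 0 of 40 over all genes and 1 adjusted over the list alone). Its members TUB1 and SPC98, fell at 75 min over all genes and 2 adjusted over the list alone. NUF2 at -0.68 ± 0.16 at 90 min and SPC98 at -0.51 ± 0.14 at 45 min had adjusted p = 0.133 and 0.342 at those times.

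At 75 min far more genes differed than at any other time, with 166 higher and 143 lower in 4P. The lowest were LYS2, SRL1 and the cell wall gene HPF1 (-1.66 ± 0.26, adjusted p = 0.00262), and among the highest was KAR4, a pheromone response transcription factor gene (1.28 ± 0.20, adjusted p = 0.00232). Pheromone response genes had 4 members that rose at 75 min over all genes and 4 adjusted over the list alone, KAR4, BAR1, FAR1 and FUS1, with a list mean of 0.38 ± 0.14 (adjusted p = 0.0924). Among stress response genes, TSL1 fell by -0.97 and the glycogen phosphorylase gene GPH1 by -0.65 ± 0.16 (adjusted p = 0.03), with a list mean of -0.33 ± 0.11 (adjusted p = 0.0905, 2 lower over all genes and 2 adjusted over the list alone). In the same 309 genes, chosen for their difference at 75 min, the differences at other times were smaller, as that choice alone would give. Those higher at 75 min had a median of 0.68 there and between 0.08 (105 min) and 0.41 (30 min) elsewhere, and those lower had -0.76 there and between -0.51 (30 min) and -0.13 (15 and 105 min).

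The size of the 75 min group rested on the handling of the arrays. It held 1000 genes with a replicate block, all 309 among them. With slide as a block it held 6 genes, 5 of them among the 309. The median absolute difference of the 309 genes was then 0.65 against 0.72 and their median SE 0.23 against 0.18. The group held 101 genes with median centring in place of loess, where 73 were higher and 28 lower. The scanner's log ratios gave 821 and the deposited series values 870. Without WT replicate 1, 4P replicate 2, 4P replicate 1 or WT replicate 2 at 75 min, 1, 10, 17 and 74 genes were left, and without any 1 of 10 arrays at 30, 45, 60 or 90 min between 178 and 202. Slide as a block left KAR4 at 1.59 (adjusted p = 0.00337) but ended the calls of HPF1 (-1.79, adjusted p = 0.0596) and GPH1 (-0.50, adjusted p = 0.241). KAR4 lost its call without WT replicate 1 at 75 min (adjusted p = 0.0861) and HPF1 without either replicate 1 array (highest adjusted p 0.0857). GPH1 lost its call without WT replicate 1 or either 4P array (highest adjusted p 0.294), with median centring (-0.48, adjusted p = 0.0931) or with the scanner's log ratios (adjusted p = 0.0926).

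**Figure D4:**
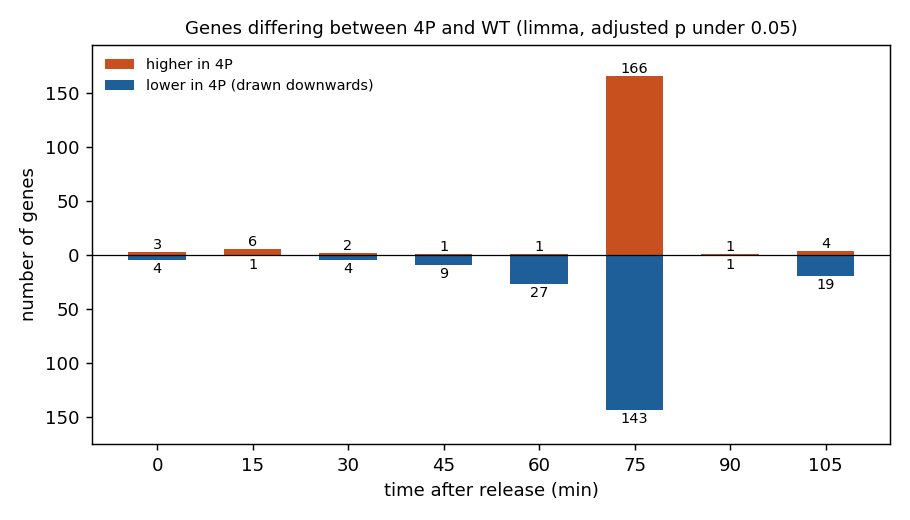
Number of genes (vertical axis) higher in 4P (orange, upwards) and lower in 4P (blue, downwards) at each time after release, with an adjusted p under 0.05 in limma. At 75 min 166 genes were higher and 143 lower, against 28 in all at 60 min and 23 at 105 min.

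At 105 min 19 genes were lower and 4 higher in 4P. Besides the MCM genes, CDC20, DBF2 and WSC4, the acid phosphatase genes PHO3 and PHO11 fell by -1.23 ± 0.24 and -0.98 ± 0.21 (adjusted p = 0.0141 and 0.044) and PRY1, which encodes a secreted sterol-binding protein, by -1.65 ± 0.27 (adjusted p = 0.00318). The hexose transporter gene HXT4 rose by 1.1 ± 0.18 (adjusted p = 0.00284). Slide as a block ended these 4 calls (PHO3 -1.20, PHO11 -1.12, PRY1 -1.73 and HXT4 0.56, with adjusted p = 0.523, 0.516, 0.226 and 1). They were also lost without single arrays. PHO11 was lost without any 1 of 15 (highest adjusted p 0.332), PHO3 without either WT array at 105 min (0.167), HXT4 without either replicate 1 array (0.119) and PRY1 without WT replicate 1 (0.0984). PHO11 had an adjusted p = 0.195 with the scanner's log ratios and 0.0826 with median centring. The count of 23 was 39 with a replicate block and 5 with slide as a block. It was 10, 11 and 11 without WT replicate 1, 4P replicate 1 and WT replicate 2 of that time, and 350 without 4P replicate 2.

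Few genes differed at the remaining times, with 7 at 0 min, 7 at 15 min, 6 at 30 min, 10 at 45 min and 2 at 90 min. At 0 min STE3, the receptor of the opposite mating type, fell by -0.97 ± 0.19 (adjusted p = 0.0436). SAG1 was at -0.64 ± 0.18 (adjusted p = 0.397, and at -0.81 with adjusted p = 0.0116 with slide as a block) and YBR184W rose by 1.69 ± 0.31 (adjusted p = 0.0277). BAT1, TOR1 and COS1 also differed at 0 min. At 15 min CDC6, COS1, CDC33, GSY1 and ESF1 rose and YNL170W fell, and at 30 min EGO4 rose by 1.13 ± 0.18 (adjusted p = 0.0085) while BAT1 and TOR1 fell. At 45 min NCA3 fell by -1.63, YGP1 by -1.5 and the histone variant gene HTZ1 by -0.76, beside TDA6, OAC1, MCM7, DBF2 and YHP1. Beside MET17, the gene called at 90 min was YHP1. With a replicate block the counts were 89 at 15 min, 31 at 30 min, 20 at 45 min and 11 at 90 min, and with slide as a block 14 at 0 min, 3 at 15 min and 2 at 30 min. The call of STE3 was lost without any 1 of 23 arrays (-1.39 to -0.54) and that of YBR184W without WT replicate 1 or 4P replicate 2 at 0 min (highest adjusted p 0.551). EGO4 lost its call without WT replicate 1 or either 4P array at 30 min (0.413) and with slide as a block (0.286). With the scanner's log ratios STE3, YBR184W and EGO4 had an adjusted p = 0.0771, 0.0669 and 0.226. Omitting arrays moved the count at 0 min between 2 (4P replicate 2) and 28 (4P replicate 1). The count at 15 min went to 299 (WT replicate 1), 50 and 17 (4P replicates 2 and 1) or down to 3. It went at 30 min to 1 or 2 without any array of that time, at 45 min to 1, 2 and 4 (4P replicate 1, WT replicate 1 and 4P replicate 2). At 90 min it went to 1 without any 1 of 23 arrays or 4 without either 4P array at 0 min.

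MET17, which encodes the enzyme that makes homocysteine, was higher in 4P at all 8 times and was the one gene called at each of them, with 4.86 ± 0.49 at 30 min (adjusted p = 1.08e-05). Its mean over the course was 4.44 ± 0.29 higher in 4P (adjusted p = 0.0149). In WT it was not well above background on either array at 0 min, so the size of its difference at that time (4.86) rests on a dim signal. It was well above background on 1 WT array each at 60 and 90 min, and on 11 arrays in WT against 16 in 4P. The sizes at those times and of the course mean therefore rest in part on dim signals too. LYS2, which encodes an enzyme of lysine synthesis, fell at 5 times, by -2.67 ± 0.48 at 75 min (adjusted p = 0.0073), and had a course mean difference of -2.32 (adjusted p = 0.261, and 0.00088 with a replicate block). With slide as a block MET17 at 30 min was at 5.44 (adjusted p = 4.45e-11) and LYS2 at 75 min at -2.11 (adjusted p = 1.18e-05). LYS2 lost its call at 75 min without WT replicate 1 or 4P replicate 2 (highest adjusted p 0.169). MET17 was the 1 gene with a shift over the course, against 654 with a replicate block, 0 with median centring (adjusted p of MET17 0.055) and 29 without the WT replicate 2 course. In limma 597 genes had an unadjusted p under 0.05 for this shift.

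The remaining lists described here did not pass at any single time, and 1 of the 18 lists is not described. Sulfur assimilation genes had a mean of 0.49 ± 0.16 at 45 min (adjusted p = 0.0786, and 0.022 with a replicate block, as at 60 and 105 min), where the median member was at 0.05. There 1 gene, MET17, was higher over all genes and 1 adjusted over the list alone. Phosphate genes were at -0.31 ± 0.10 at 105 min (adjusted p = 0.0619, and 0.00669 with a replicate block) and at -0.26 at 45 min (0.104, and 0.022), with 2 lower over all genes at 105 min and 4 adjusted over the list alone. Strain marker genes, of which 5 of 6 passed the filter on dim probes, had 1 member called at several times, LYS2. The lowest adjusted p over the 8 times was 0.31 for alpha and meiotic cell genes, 0.323 for ribosome biogenesis genes, 0.477 for ribosomal protein genes, 0.159 for DNA damage genes and 0.518 for strain markers. Ribosome biogenesis, ribosomal protein and DNA damage genes had 0 members past the limma test over all 8 times, over all genes or adjusted over the list alone (1203 of all genes had an unadjusted p under 0.05). With a replicate block 3 ribosome biogenesis genes passed it. MFA2, a mating pheromone gene, fell by -1.35 ± 0.23 at 60 min (adjusted p = 0.00569), BAR1 was at 0.89 ± 0.23 at 90 min (adjusted p = 0.227) and HSP12 at -0.57 ± 0.17 at 90 min (adjusted p = 0.315). The MFA2 call ended without WT replicate 1 or either 4P array at 60 min (highest adjusted p 0.135), with slide as a block (-1.56, adjusted p = 0.064) and with the scanner's log ratios (adjusted p = 0.135).

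Differences between the strains depended on time for 5 genes and 4 lists. The genes were DBF2 and CDC6 (adjusted p = 0.0036 for both), MCM5 (0.0168), and MCM7 and the pheromone receptor gene STE2 (0.0453 for both). STE2 was at 0.82 at 15 min, -0.79 at 45 min and -1.08 at 105 min. The lists were early cell cycle box genes (adjusted p = 4.48e-05), CLB2 cluster genes (0.00254), MBF-type genes (0.00278) and SBF-type genes (0.0229). With a replicate block 30 genes and 8 lists depended on time, and with slide as a block 13 genes and 7 lists, with early cell cycle box genes at 0.000226. Without single arrays the gene count ran from 2 (WT replicate 2 at 60 or 105 min, or 4P replicate 2 at 75 min) to 18 (4P replicate 2 at 105 min), and the list count reached 7 without 4P replicate 1 at 0 min. In the test over all 8 times together the means of 6 lists differed, those 4 lists, the mutated transcription factor genes (adjusted p = 0.011) and sulfur assimilation genes (adjusted p = 0.00294). With a replicate block histone genes (adjusted p = 0.0497), Hcm1 targets (0.0102), stress response genes (0.0412) and phosphate genes (0.00563) passed it as well. Differences at any time were found for 313 genes (1004 with a replicate block, 23 with slide as a block, 110 with slide as a random block). The main fit takes the arrays of 1 time course as independent. With the time course as a random block (correlation 0.241) 73 genes differed at any time, and 47 genes and 8 lists depended on time. Leaving out single arrays moved the count of 313 as well. Over the times, 392 calls fell on 355 genes, 21 of which were called at 2 or more times.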

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

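The tests in this section address patterns already seen in the main results. The test of the early cell cycle box genes with slide as a block was chosen before its own outcome was seen. So were those of stage and the test without 1 array. The gene length test of the 75 min group was chosen only after.

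Differences between 4P and WT that changed over time were found for 5 genes by an interaction term in limma. The adjusted p of the dependence on time was 0.0036 for DBF2, 0.0036 for CDC6, 0.0168 for MCM5, 0.0453 for MCM7 and 0.0453 for STE2. DBF2 was at -0.90 at 45 min and -1.28 at 105 min. CDC6 was at 1.05 at 15 min and 0.84 at 75 min. STE2 was at 0.82 at 15 min and -1.08 at 105 min.

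The same term picked out 4 gene lists. Its adjusted p was 4.48e-05 for early cell cycle box genes, 0.00254 for CLB2 cluster genes, 0.00278 for MBF-type genes and 0.0229 for SBF-type genes. CLB2 cluster genes were lower at 90 and 105 min, MBF-type genes lower at 60 min and higher at 90 min, and SBF-type genes lower at 75 min. In camera with an estimated correlation 3 of these calls were lost. They were CLB2 cluster genes at 105 min (adjusted p = 0.0631), MBF-type genes at 60 min (adjusted p = 0.0636) and SBF-type genes at 75 min (adjusted p = 0.434). A difference in stage was not tested for the CLB2, MBF and SBF lists and stays open.

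Early cell cycle box genes were lower in 4P at 45, 60 and 105 min. A slide effect that is constant on a slide would not leave a dependence on time once slide is a block, and the adjusted p was then 0.000226. A different stage of the cycle was not the whole source either, since 80.8% of the mean over the 3 times stayed when each 4P sample was set against its best matching WT time (-0.63 at equal times and -0.51 at matching times). At 45 min the best match was 45 min itself, so -0.52 stayed by construction, and where the match moved the difference went from -0.46 to -0.31 at 60 min and from -0.90 to -0.70 at 105 min. A difference in stage therefore stays open as a part of the fall. The 4P array at 105 min, replicate 1, was not the source at that time, since without it the difference was -0.77 (adjusted p = 0.000492). The genotype, and any other difference between 1 strain of each genotype, stays open and was not tested further.

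At 75 min 309 genes differed, against at most 28 at any other time. A gene length trend was not the whole source, since 237 genes passed after its removal and 319 before it (genes with a known length), against at most 26 at another time. A shift in stage was not either, since at least 82.6% of the squared difference stayed at every WT minute. At the best matching WT time, which was 75 min itself, 100% stayed by construction, which carries no information. A slide effect stays open. In the contrast of 75 min against the mean of 30, 60 and 90 min, whose samples share slide pairs, a constant slide effect cancels, and 1 gene passed in limma (247 had an unadjusted p under 0.05). That low count goes with a slide effect and equally with a genotype difference alike at these times. A median share of 0.573 of the difference was left, with the sign kept in 307 of 309 genes, but the genes were chosen for their difference at 75 min, which leaves a share by itself. On the slide that held both genotypes at 45 min, 292 of the 309 genes had the sign they had at 75 min, with a median share of 0.548 and r = 0.844 across genes, which are not independent replicates. These values argue against a slide effect as the whole source but come from 1 pair of arrays. Across slides in replicate 2 the share was 0.149, with 230 genes of the same sign.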

How the results depend on the processing

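Slide as a random block, the removal of a gene length trend, the omission of the 2 arrays with the most outlier spots (4P replicate 1 at 15 and 105 min) and the sulfur list without MET17 were chosen after seeing the data. All other alternatives were chosen before the data were examined. The cause was not tested for any of the moves below. Where 1 array was left out, its group kept a single dye orientation. Counts that moved and calls that ended in those fits can therefore come from the dye effect as well as from fewer arrays.

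Aquantile scaling changes mean intensities and leaves the log ratios as they are, so it could move no result and carries no information. Counts over time in WT and 4P stayed within 1.5 times under every alternative run. So did all results with no filter on dim probes (6225 genes in place of 6205) and with the single brightest probe per gene (29 genes with several probes), settings that touch few genes. Under the other alternatives the counts of genes that differ between the strains did not. In the main setting they were 392 over all times, made of 7, 7, 6, 10, 28, 309, 2 and 23 at 0 to 105 min, with 313 genes at any time, 5 genes that depend on time, 10 list shifts, 4 lists that depend on time and 1 course shift.

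With a replicate block the counts were 1241 over all times, 89 at 15 min, 31 at 30 min, 20 at 45 min, 43 at 60 min, 1000 at 75 min, 11 at 90 min and 39 at 105 min, 1004 genes at any time, 30 that depend on time, 18 list shifts, 8 lists that depend on time and 654 course shifts. Of the genes tested singly 7 more passed with the replicate block, among them HCM1 at 75 min (adjusted p = 0.0475), YOX1, CLN2, CLB2, SMC3 and PRI2, and it changed no other call of these genes.

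With slide as a fixed block they were 45 over all times, 14 at 0 min, 3 at 15 min, 2 at 30 min, 4 at 60 min, 6 at 75 min and 5 at 105 min, 23 at any time, 13 that depend on time, 2 list shifts and 7 lists that depend on time. Slide as a random block gave 15 at 0 min, 11 at 15 min, 110 at any time, 39 that depend on time and 8 lists. The time course as a random block gave 73 at any time, 47 that depend on time and 8 lists. Slide as a block was not run for the means over the course.

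The scanner's log ratios gave 857 over all times, 1 at 0 min, 1 at 15 min, 3 at 30 min, 2 at 45 min, 9 at 60 min, 821 at 75 min, 1 at 90 min, 78 at any time, 0 that depend on time (253 at an unadjusted p under 0.05 in the main setting, limma) and 21 list shifts, and 6 lists with the same peak in all courses, against 10. The deposited series values gave 900 over all times, 0 at 0, 15, 30 and 90 min (limma, 473, 887, 777 and 401 unadjusted in the main setting), 1 at 45 min, 12 at 60 min, 870 at 75 min, 103 at any time, 18 list shifts and 0 course shifts. Median centring gave 153 over all times, 1 at 0 min, 12 at 15 min, 3 at 30 min, 12 at 60 min, 101 at 75 min, 1 at 90 min, 194 at any time and 0 course shifts.

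A stricter filter gave 3 at 15 min, 0 at 90 min and 0 course shifts. A trended and robust prior gave 1 at 0 min, 3 at 30 min, 5 at 45 min, 1 at 90 min, 2 that depend on time and 0 course shifts. Course shifts reached 1758 with all 32 arrays as independent. Removing the length trend gave 3 at 0 min and 9 that depend on time. Without the 2 arrays with the most outlier spots there were 19 at 15 min, 493 at 75 min, 4 at 90 min, 14 at 105 min and 2 that depend on time. List shifts numbered 36 in camera with a preset correlation and 6 with an estimated one.

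Directions turned in 2 cases, neither called in any setting. WHI5 at 60 min was at -0.0624 with median centring (adjusted p = 0.998) and TOS4 at 60 min at 0.13 with slide as a fixed block (adjusted p = 0.998). Of 2247 recomputed differences of named genes 2059 kept their direction and call, 165 lost the call and 21 gained one. The 2059 include differences that were uncalled and stayed so, and 49 with Aquantile. They therefore do not measure how often calls held. Of 490 recomputed list shifts 424 kept both and 66 lost the call. The 424 include 10 with Aquantile and 10 with the sulfur list without MET17, settings that could change none of these means.

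Leaving out 1 array at a time, the lone array of a group being assumed to vary like the others, gave 1688 to 2378 genes over time in WT, 2058 to 2695 in 4P and 74 to 788 over all times. By time the ranges were 2 to 28 at 0 min, 3 to 299 at 15 min, 1 to 8 at 30 min, 1 to 12 at 45 min, 4 to 32 at 60 min, 1 to 419 at 75 min, 1 to 4 at 90 min and 10 to 350 at 105 min. Genes at any time ran from 146 to 542, genes that depend on time from 2 to 18, list shifts from 7 to 17, lists that depend on time from 3 to 7, and course shifts from 2 to 29 when 1 of 4 courses was left out.

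Signal over background had a median of 26.5 in the sample channel and a lowest value of 6.67, which limits ratios of dim genes such as MET17 in WT.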

Other observations

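All tests of MET17, LYS2 and the lysine genes were chosen after the results were seen, and the splits of the time courses before.

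MET17 was higher and LYS2 lower in 4P at all 8 times. A response of the sulfur pathway would raise the other sulfur assimilation genes too, and their mean shift over the course was -0.0141 (SE 0.0352, 10 genes, 4 of them positive). All 32 differences over times and replicates had the sign of their gene's shift over the course, positive for MET17 and negative for LYS2, which restates the pattern and tests nothing. A strain difference outside the 4 mutated genes, at genes that serve as auxotrophic markers in laboratory yeast, cannot be told apart from an effect of the mutant factors, because the design has 1 strain per genotype.

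The median of the other genes of lysine synthesis lay lower in 4P. Their median shift over the course was -0.28 in the replicate with the smaller shift and -0.31 in the other, and 7 of 8 genes were lower in both replicates. As low a value was reached by 0% of 10000 random gene sets of that size. Genes of 1 pathway can move together from culture to culture, unlike random genes. That share therefore does not measure the support for a genotype effect. The other LYS genes ran from LYS20 at -0.66 to LYS14 at -0.03 and LYS5 at 0.04. Taken singly, 5 of these genes had values on every array and none of the 5 passed for a shift of the course means in limma (lowest adjusted p 0.446), while LYS1 and LYS4 passed with a replicate block (adjusted p = 0.0166 and 0.0204). In the mean of the differences at the 8 times, with all arrays as independent, LYS1, LYS4, LYS9, LYS20 and LYS21 passed (adjusted p from 0.000865 to 0.00772). LYS2 itself shifted by -2.32 over the course, far beyond the lowest of these other genes, LYS20 at -0.66. These values argue against an equal fall of the whole lysine pathway as the explanation of the low LYS2 level. The source of the smaller fall of the other genes was not tested.

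Regrouping the 4 time courses into pairs gave 3 splits, and the real one was the 1 with as many genes at any time as the genotypes (313), against 56 for the split by dye orientation as the highest other. The splits are too few for a share under 0.05.

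TOS4 and YHP1 were below the reference on all 32 arrays. The ratios compare tagged strains with an untagged reference strain.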
